A study of Mus musculus with 18 samples.

How the data were processed

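Bulk RNA sequencing was done on islets of 18 mice, about 165 islets per mouse, with 1 library for each mouse. Per the labels, RNA was taken with a column kit, had RIN values of 8.4 to 9.5, and was made into TruSeq libraries after Ribo-Zero depletion of ribosomal RNA. The values were estimated counts per gene symbol, not normalised, per the submitters' processing notes and the table itself. The notes name STAR, HTSeq, GRCm38 and mm10 without versions, and the step that gave fractional values, the annotation and the strand setting are not given in the sources used here. With no tolerance allowed, 182064 values were not whole numbers, which is 39.2% of the values above 0, and they were rounded to whole numbers before testing. Of 54186 gene symbols, 49732 matched symbols of GENCODE M21 and 38347 matched RefSeq, which gave positions on GRCm38. Samples are named by genotype and a number in the order of the labels, which pairs nothing, so no paired test was made. Every within-group pair of libraries differed by far more than counting error (45 pairs, chi-square per degree of freedom 28.1 to 271), so none was a repeat of another. Xist had 5 to 42 counts and Ddx3y 10003 to 17344 in all 18 libraries, so a covariate for sex was not run.

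Counts were analysed with edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr by genotype (20244 genes kept) and a quasi-likelihood fit of all 18 libraries with 1 mean per genotype. Tests were two-sided and p values were adjusted by Benjamini-Hochberg within a comparison, with a gene called at an adjusted p under 0.05. In the text, edgeR adjusted p denotes this value. Levels are given as CPM, counts scaled to the library total times its TMM factor, and log2 CPM used a prior count of 2. Total counts per library were 110 to 166.2 M. The 95% intervals come from the fit, and any precision derived from counts covers counting error only. The 32 gene lists were written from textbook knowledge and tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 32 lists of a comparison. Camera with an estimated correlation and fry were run beside it. Fry tests whether the genes of a list move one way on balance and does not compare them with other genes. It called 20 lists for hIAPP against WT, 13 for hIAPP against rIAPP and 19 for rIAPP against WT. Scores per library were the mean log2 CPM over a list, compared by exact two-sided permutation tests of 6 against 6 libraries.

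Named genes were chosen by rule. They were Iapp, the 10 higher and 10 lower called genes with the largest log2 fold change and a mean of at least 1 CPM in the higher group, and up to 4 members with the smallest p of each list called by camera and of the first 3 lists. For the genes changed in hIAPP against both genotypes, the 10 with the smallest larger p were taken. Gene models without a proper name were skipped. Any gene outside the rule is marked where it appears, and some genes that the rule names are not reported here. Overlaps were compared with independence, with 10 simulations of unchanged groups that share libraries, and with 20 splits of the shared group.

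The comparisons, lists, named-gene rule and most of the alternatives were fixed before the data were examined. Alternatives were DESeq2 1.42.0, limma-voom with sample weights, other scaling factors, library totals alone, other filters and thresholds, a robust fit, fits of only the 2 genotypes compared, removal of the 10 most abundant genes or of acinar markers, the acinar score, mouse number or 1 surrogate variable (sva 3.50.0) as a covariate, a prior count of 0.5, and leaving out each library. Runs without hIAPP 5 and hIAPP 6 and with counts thinned to the smallest library, and medians for further list scores, were added after the data were seen. For chance, 100 splits of the libraries were drawn per comparison, of which the first 60 had been seen before the rest were added. The pipeline was tested on simulated data. Of 50 simulated genes per fold size, it recovered 10% at 1.2-fold, 82% at 1.5-fold, 96% at 2-fold and 100% at 4-fold for hIAPP against WT, and called 8 unchanged genes of 19795. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Counts of genes with near-identical copies (Ins1 and Ins2, the hemoglobin genes, Lyz2, Ceacam10, Pramel34, Reg3a, Cyp2j5 and ribosomal proteins) depend on how shared reads were assigned, and those of Plut, which lies antisense to Pdx1, on the strand setting.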

Results

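RNA was sequenced from pancreatic islets of 18 mice aged 6 weeks on the FVB background, 1 library per mouse and 6 per genotype. Islet amyloid polypeptide (IAPP) is a peptide hormone that beta cells secrete together with insulin. The hIAPP mice carried a transgene for the human peptide, which is prone to aggregate, and the rIAPP mice a transgene for the rodent peptide, which is not. Both transgenes were driven in beta cells by the insulin II promoter, and WT mice carried neither. The values were estimated counts per gene symbol. WT libraries held 156 ± 8.89 M counts (mean ± SD, n = 6, range 144 to 166.2), hIAPP libraries 128 ± 13.4 M (110 to 142) and rIAPP libraries 138 ± 10.5 M (128 to 158). The hIAPP total was below WT (exact permutation p = 0.00216, the smallest that 6 against 6 libraries can give; adjusted over 24 library tests, 0.0130), as was the rIAPP total (exact p = 0.0152, adjusted 0.0404).

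Islet preparations can hold exocrine tissue, and the libraries differed in it. Acinar cell markers, the genes of digestive enzymes and their regulators, made up 0.243% ± 0.129 of counts in WT (SD, n = 6), 1.03% ± 0.746 in hIAPP (exact p against WT = 0.00433, adjusted 0.0208) and 1.27% ± 0.670 in rIAPP (exact p against WT = 0.00216, adjusted 0.0130). The insulin genes Ins1 and Ins2 together made up 9.49% ± 0.435 in WT, 7.64% ± 1.88 in hIAPP (exact p against WT = 0.0238, adjusted 0.0519) and 5.12% ± 0.720 in rIAPP (exact p against WT = 0.00216, adjusted 0.0130). Rn18s-rs5, an entry for a sequence related to the ribosomal RNA gene Rn18s, made up 0.0350% in WT, 0.0513% in hIAPP and 0.155% in rIAPP (exact p of rIAPP against WT = 0.00216, adjusted 0.0130). Rn7s1, which encodes the RNA of the signal recognition particle, took 22.8% of counts over all libraries. On the first principal component the rIAPP libraries lay between 29.6 and 45.0 and all WT and hIAPP libraries between -25.8 and -15.0. On the second component, hIAPP 5 (34.6) and hIAPP 6 (41.9) lay apart from the other hIAPP libraries (3.11 to 15.3). These 2 libraries had acinar shares of 1.44% and 2.33% and insulin shares of 4.71% and 6.05%.

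**Figure D1:**
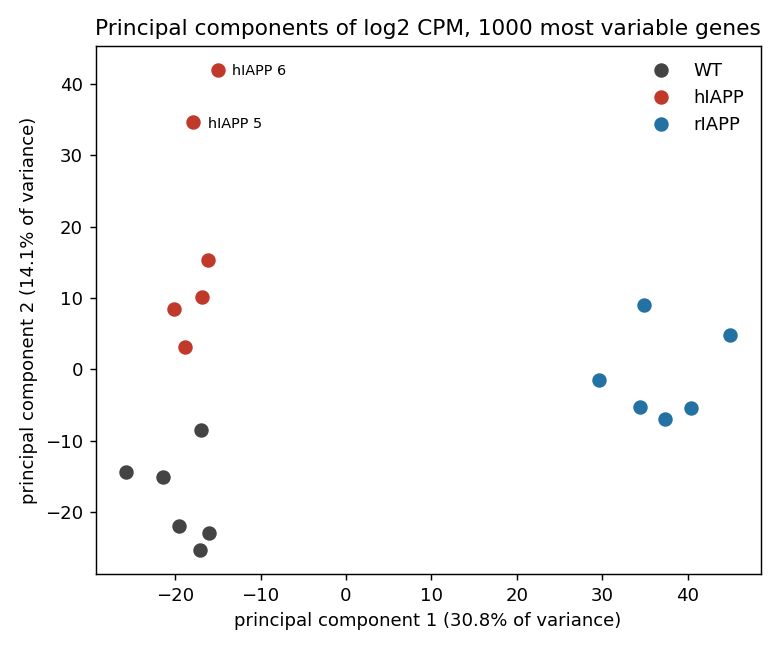
Scores of the 18 libraries on the first (30.8% of variance) and second (14.1%) principal components of log2 CPM of the 1000 most variable genes, 1 dot per library, coloured by genotype. The rIAPP libraries are separated from WT and hIAPP on the first component, and hIAPP 5 and hIAPP 6 lie highest on the second.

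The comparison of hIAPP with WT islets asked what the human transgene changed at an age of 6 weeks. Islets of hIAPP mice held more RNA of macrophage genes, of the integrated stress response and of Sema5a, and less RNA of cholesterol synthesis enzymes. Lyz2, which encodes the lysozyme of macrophages and other myeloid cells, averaged 221 ± 72.9 CPM (SD, n = 6) in hIAPP and 11.7 ± 1.47 in WT, a log2 fold change of 4.24 ± 0.18 (SE, edgeR adjusted p = 5.08e-12). Sema5a, which encodes a membrane-bound semaphorin, averaged 850 ± 78.9 CPM in hIAPP and 11.7 ± 1.70 in WT (log2 fold change 6.18 ± 0.13, edgeR adjusted p = 4.27e-18). Hmgcs1, which encodes the HMG-CoA synthase of the mevalonate pathway, averaged 55.4 ± 8.11 CPM in hIAPP and 92.0 ± 13.5 in WT (log2 fold change -0.73 ± 0.11, edgeR adjusted p = 1.60e-04). For each of these 3 genes the 6 hIAPP libraries lay on the same side of all 6 WT libraries.

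Of the 13 macrophage markers measured, 12 rose and 1 did not pass, with 13 higher when adjusted over the list alone (camera adjusted p = 1.07e-20, adjusted p = 0.0689 with an estimated correlation). Cd68, a lysosomal membrane protein of macrophages, rose by a log2 of 2.79 ± 0.25 (edgeR adjusted p = 4.43e-07), and Tyrobp, a signalling adaptor of myeloid cells, by 2.03 ± 0.18 (edgeR adjusted p = 2.93e-07). Gpnmb, a glycoprotein of lipid-laden and phagocytic macrophages, rose by 4.78 ± 0.43, and Atp6v0d2, a subunit of the lysosomal proton pump, by 7.09 ± 0.73 (edgeR adjusted p = 3.64e-07 and 1.99e-06). The Atp6v0d2 level was 13.7 CPM in hIAPP 5, 1.06 to 4.42 in the other hIAPP libraries and at most 0.0791 in WT. Of 7 lymphocyte markers, 3 rose (Cd4, Cd22 and Il7r) and 4 did not pass, with 3 higher when adjusted over the list alone (camera adjusted p = 0.00555, adjusted p = 0.0813 with an estimated correlation). Cd4, a coreceptor of helper T cells, rose by 3.46 ± 0.34 from a WT mean of 0.197 CPM (edgeR adjusted p = 8.87e-07). The lymphocyte markers Cd3g and Cd2 did not pass. Cd4 was highest in hIAPP 5 (4.70 CPM, 1.44 to 2.12 in the other hIAPP libraries). So was the macrophage marker Cd68 (28.2 CPM, 7.33 to 14.9 in the others). The Cd4 level was therefore not shown to come from T cells. In the autophagy and lysosome list, 13 of 25 genes rose, 1 fell and 11 did not pass, the same counts as when adjusted over the list alone (camera adjusted p = 1.67e-06, adjusted p = 0.0863 with an estimated correlation). Its members with the smallest p encode lysosomal hydrolases: Ctsd rose by 1.08 ± 0.12 and Ctsb by 0.91 ± 0.10 (edgeR adjusted p = 3.08e-06 and 7.32e-06). Macrophage marker scores were higher in the same libraries, by 1.55 log2 units (exact p = 0.00216, the smallest possible).

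Cholesterol synthesis enzymes fell as a group: 16 of 20 fell, none rose and 4 did not pass, with 18 lower when adjusted over the list alone. Their median log2 fold change was -0.49 (camera adjusted p = 2.47e-11, adjusted p = 0.156 with an estimated correlation). The title of the series names cholesterol homeostasis, so this list is not independent evidence of its direction. Idi1, the isopentenyl diphosphate isomerase, fell by 0.91 ± 0.15 on the log2 scale from 23.2 ± 3.39 CPM in WT, and Cyp51 and Lss, enzymes of the later sterol steps, fell by 0.65 ± 0.10 and 0.51 ± 0.08 (edgeR adjusted p = 3.44e-04, 2.29e-04 and 2.70e-04). The mean log2 CPM of the list was 4.19 ± 0.170 in hIAPP and 4.65 ± 0.0881 in WT (SD, n = 6, exact p = 0.00216). As a covariate, the acinar score left 8 enzymes passing (median -0.45), and without hIAPP 5 and hIAPP 6 10 passed (median -0.41).

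Sterol uptake and SREBP control genes went both ways, with 4 of 16 higher, 6 lower and 6 not passing, and 6 higher and 7 lower when adjusted over the list alone (camera adjusted p = 0.796). Their median (0.03) and mean (-0.10) differed in sign. Stard4, a sterol transport protein, fell by 0.77 ± 0.15 on the log2 scale (edgeR adjusted p = 0.00147), and Lipa, the acid lipase that frees cholesterol in lysosomes, rose by 0.92 ± 0.11 (edgeR adjusted p = 1.93e-05). Among 15 genes of cholesterol efflux, esterification and oxysterols, 5 rose, none fell and 10 did not pass, with 6 higher when adjusted over the list alone (camera adjusted p = 0.00595, adjusted p = 0.0863 with an estimated correlation). Apoe, a lipid-carrying protein that macrophages also make, rose by 1.75 ± 0.09, from 400 ± 22.5 to 1341 ± 219 CPM (SD, n = 6, edgeR adjusted p = 1.99e-10), and Abca1, a cholesterol exporter, rose by 0.38 ± 0.10 (edgeR adjusted p = 0.0151). The Abca1 call was lost in 4 of the alternative runs. Macrophage (1.55) and acinar (1.66) scores were higher in the same libraries. Of 17 genes of fatty acid synthesis and desaturation, 6 fell, 2 rose and 9 did not pass, the same counts as when adjusted over the list alone (camera adjusted p = 0.0190, adjusted p = 0.194 with an estimated correlation). The desaturases Scd2 and Fads2 fell by 0.91 ± 0.11 and 0.69 ± 0.08 on the log2 scale (edgeR adjusted p = 9.64e-06 and 3.72e-06).

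Integrated stress response genes, targets of the transcription factors ATF4 and CHOP, rose in hIAPP: 21 of 24 rose, none fell and 3 did not pass, with 23 higher when adjusted over the list alone and a median of 0.86 (camera adjusted p = 7.10e-20, adjusted p = 0.0689 with an estimated correlation). Trib3, a pseudokinase induced by ATF4 and CHOP, rose by 3.02 ± 0.32, and Ddit3, which encodes CHOP itself, by 1.36 ± 0.17 (edgeR adjusted p = 2.48e-06 and 1.78e-05). Of 26 ER chaperone and unfolded protein response genes, 6 rose, none fell and 20 did not pass, with 7 higher when adjusted over the list alone (camera adjusted p = 0.00451, adjusted p = 0.289 with an estimated correlation). Among the 6 were Derl3 (1.09 ± 0.16, edgeR adjusted p = 1.04e-04), Creld2 (0.31 ± 0.05, edgeR adjusted p = 1.45e-04) and Herpud1 (0.60 ± 0.09, edgeR adjusted p = 2.16e-04). Cytosolic heat shock genes rose in 4 of 15 cases, with 11 not passing and 4 higher when adjusted over the list alone (camera adjusted p = 0.00507, adjusted p = 0.362 with an estimated correlation). Among the 4 were Cryab (0.73 ± 0.12, edgeR adjusted p = 3.48e-04), a small heat shock protein, and the chaperone Hsph1 (0.75 ± 0.21, edgeR adjusted p = 0.0171). Among 14 p53 targets, 6 rose and 8 did not pass, with 8 higher when adjusted over the list alone (camera adjusted p = 7.56e-04, adjusted p = 0.221 with an estimated correlation). The cell cycle inhibitor Cdkn1a rose by 1.10 ± 0.26 (edgeR adjusted p = 0.00675). Acinar marker scores were higher in these libraries by 1.66 (exact p = 0.00649), and with that score as a covariate 9 stress response genes passed (median 0.50). In the alternative runs the Creld2 call was lost in 1, and the Hsph1 and Cdkn1a calls in 2 each. Derl3, Herpud1 and Cryab kept their calls.

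Beta cell identity and function genes fell in 11 of 21 cases, with none higher, 10 not passing and 14 lower when adjusted over the list alone (median -0.32, camera adjusted p = 1.67e-06, adjusted p = 0.233 with an estimated correlation). Mafa, a transcription factor of mature beta cells, fell by 1.29 ± 0.18 on the log2 scale, from 305 ± 50.9 to 125 ± 37.6 CPM (SD, n = 6, edgeR adjusted p = 8.61e-05). Aldh1a3, an aldehyde dehydrogenase of dedifferentiated beta cells, rose by 3.47 ± 0.28 (edgeR adjusted p = 7.14e-08). Given the acinar score as a covariate, 1 beta cell identity gene passed (median of the list -0.16), and without hIAPP 5 and hIAPP 6 3 did (median -0.21). The exocytosis and calcium channel list had 7 of 22 genes lower, none higher and 15 not passing, with 7 lower when adjusted over the list alone (camera adjusted p = 0.0467, adjusted p = 0.233 with an estimated correlation). Chga, a granule protein of endocrine cells, fell by 0.70 ± 0.13 (edgeR adjusted p = 0.00144). Npy, a neuropeptide also made by immature beta cells, and Nnat, an imprinted gene for a small membrane protein, fell by 1.69 ± 0.15 and 1.61 ± 0.25 on the log2 scale (edgeR adjusted p = 3.64e-07 and 1.68e-04). The endogenous Iapp gene (chromosome 6, 142298425 to 142303820) fell by 0.42 ± 0.11 (95% interval -0.66 to -0.18, edgeR adjusted p = 0.0156), from 34206 ± 5459 to 25572 ± 3782 CPM. Given that covariate, the Iapp value was -0.28 (edgeR adjusted p = 0.335). The human sequence differs from the mouse gene, so Iapp does not check the genotype labels.

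Markers of other cell types moved in both directions. Acinar markers rose in 21 of 23 cases, with 22 higher when adjusted over the list alone and 2 not passing (camera adjusted p = 2.90e-12, adjusted p = 0.233 with an estimated correlation). The elastase gene Cela1 rose by 1.82 ± 0.40 (edgeR adjusted p = 0.00383). Without hIAPP 5 and hIAPP 6, 2 acinar markers passed (median 1.23). Stellate and mesenchymal markers rose in 8 of 12 cases, with 4 not passing and 9 higher when adjusted over the list alone (camera adjusted p = 1.26e-05, adjusted p = 0.235 with an estimated correlation). Col1a2, a chain of type I collagen, rose by 0.98 ± 0.20 and Pdgfrb, a receptor of pericytes, by 0.56 ± 0.08 (edgeR adjusted p = 0.00277 and 8.30e-05). Schwann cell markers rose in 5 of 8 cases and 1 fell, with 6 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.00184, adjusted p = 0.194 with an estimated correlation). Gfap, an intermediate filament of glia, rose by 0.86 ± 0.22 (edgeR adjusted p = 0.0114). Of 10 ductal markers 6 fell and 4 did not pass, with 6 lower when adjusted over the list alone (camera adjusted p = 0.00199, adjusted p = 0.0963 with an estimated correlation). The secreted matrix protein gene Spp1 fell by 0.73 ± 0.11 on the log2 scale (edgeR adjusted p = 1.60e-04). Of 12 endothelial markers 3 fell, 9 did not pass and 3 were lower when adjusted over the list alone (camera adjusted p = 0.00521, adjusted p = 0.289 with an estimated correlation). Kdr, a VEGF receptor, fell by 0.31 ± 0.07 (edgeR adjusted p = 0.00607). Of 6 erythroid markers 3 fell, 3 did not pass and 4 were lower when adjusted over the list alone (camera adjusted p = 0.00500, adjusted p = 0.233 with an estimated correlation).

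Interferon response genes had 2 of 22 higher, 6 lower and 14 not passing, with 2 higher and 8 lower when adjusted over the list alone (camera adjusted p = 0.0123, adjusted p = 0.435 with an estimated correlation). Irf7, a transcription factor of the response, fell by 0.62 ± 0.10 and the chemokine gene Cxcl10 rose by 3.12 ± 0.54 (edgeR adjusted p = 3.45e-04 and 5.47e-04). Of 31 proteasome genes, 3 fell, 1 rose and 27 did not pass, as when adjusted over the list alone (camera adjusted p = 0.00469, adjusted p = 0.529 with an estimated correlation). Psmd1, a subunit of the regulatory particle, fell by 0.27 ± 0.06 (edgeR adjusted p = 0.00607). Of 37 respiratory chain genes, 2 fell, 1 rose and 34 did not pass, with 1 lower when adjusted over the list alone (camera adjusted p = 0.0426, adjusted p = 0.781 with an estimated correlation). Over all genes, 3208 of 20244 passed, 1683 higher and 1525 lower, of which 432 and 145 changed at least 2-fold. With the preset correlation 21 of the 32 lists were called, and none held with an estimated one. The estimated correlation was 0.509 for cholesterol synthesis enzymes and 0.911 for acinar markers, far above the preset of 0.01. Camera p values at the preset are therefore too small where the genes of a list move together. With the acinar score as a covariate 792 genes passed, and without hIAPP 5 and hIAPP 6 1675 passed.

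**Figure D2:**
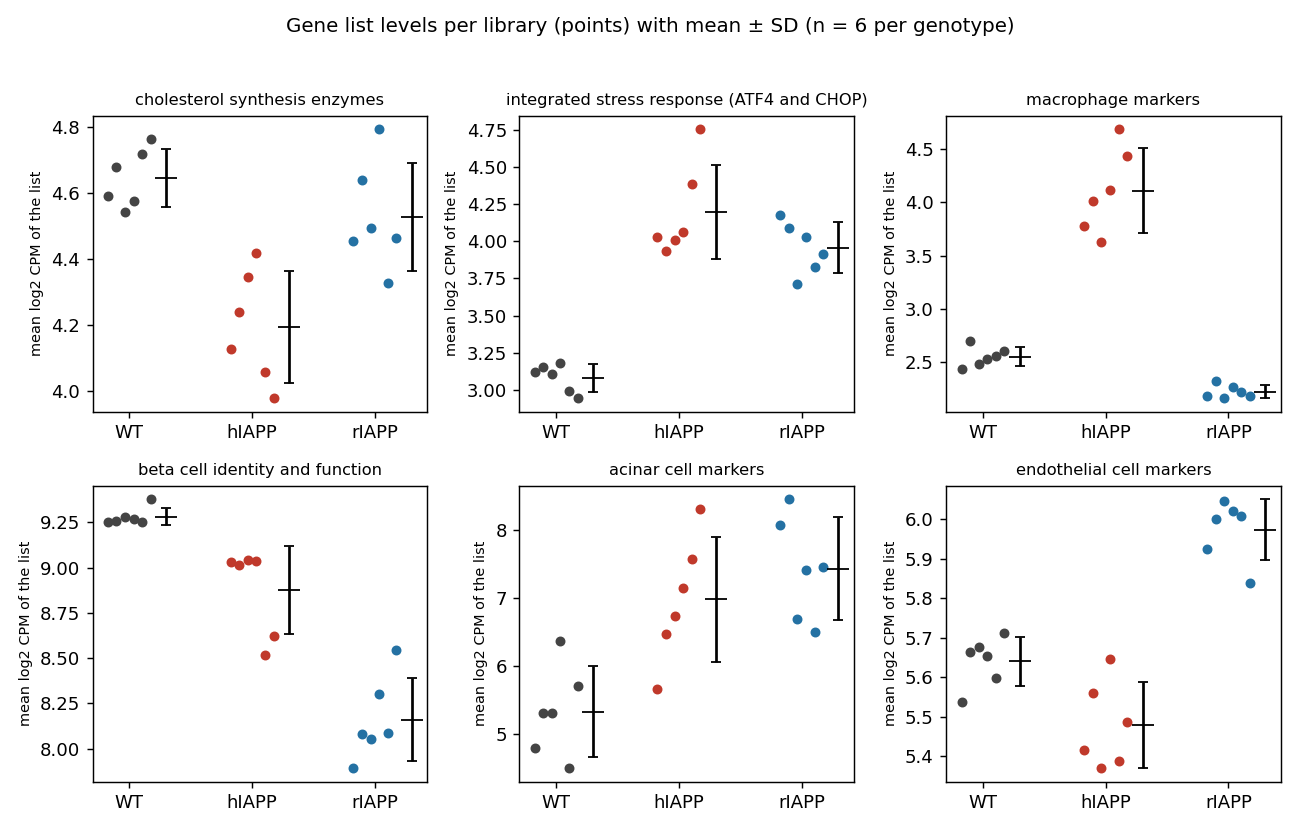
Mean log2 CPM over each of 6 gene lists (cholesterol synthesis, integrated stress response, macrophage, beta cell identity, acinar and endothelial genes) in every library, with the mean and SD of each genotype (n = 6). Macrophage scores are highest in hIAPP, beta cell identity scores lowest in rIAPP, and acinar scores higher in both transgenic genotypes than in WT.

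The comparison of hIAPP with rIAPP asked what set the human peptide apart from a rodent peptide made under the same promoter. Macrophage and lysosomal genes were again higher in hIAPP and cholesterol synthesis enzymes lower, while beta cell identity genes were higher and endothelial markers lower. Sema5a differed by a log2 of 6.96 ± 0.13 (edgeR adjusted p = 1.42e-18), with an rIAPP mean of 6.85 ± 1.04 CPM (SD, n = 6). Abcc8, the sulfonylurea receptor subunit of the beta cell potassium channel, averaged 721 ± 35.8 CPM in hIAPP and 266 ± 37.1 in rIAPP (log2 1.44 ± 0.09, edgeR adjusted p = 2.20e-10), beside 676 ± 75.7 in WT. Bmp3, a secreted factor of the BMP family, averaged 6.85 ± 1.22 CPM in hIAPP and 108 ± 19.5 in rIAPP (log2 -3.97 ± 0.14, edgeR adjusted p = 3.51e-14).

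Of the 13 macrophage markers, 12 were higher and 1 lower in hIAPP than in rIAPP, as when adjusted over the list alone (camera adjusted p = 1.06e-14, adjusted p = 0.0876 with an estimated correlation). C1qa, a complement component made by macrophages, differed by 1.56 ± 0.10 and Ctss, a cathepsin of antigen-presenting cells, by 2.08 ± 0.14 (edgeR adjusted p = 4.65e-10 and 1.02e-09). Lymphocyte markers were higher in 4 of 7 cases with 3 not passing, 4 when adjusted over the list alone (camera adjusted p = 8.26e-04). This call held narrowly with an estimated correlation (adjusted p = 0.0498), where the estimate over the 7 genes was negative (-0.0665). Cd22, a B cell receptor protein, differed by 2.77 ± 0.21 and Cd79a, part of the B cell antigen receptor, by 1.34 ± 0.27 (edgeR adjusted p = 3.88e-09 and 7.02e-04). The Cd79a level was 19.2 to 19.8 CPM in hIAPP 1 to 3, while hIAPP 5 and hIAPP 6 (6.34 and 6.31) lay within the rIAPP range (3.61 to 6.74). In WT it was 13.3 to 17.6 CPM, where Cd79b, another marker of the list, had 0.0922 to 0.187. The Cd79a level was therefore not shown to come from B cells. In the autophagy and lysosome list 16 of 25 genes were higher, 1 lower and 8 not passing, with 17 higher and 1 lower when adjusted over the list alone (camera adjusted p = 1.11e-06, adjusted p = 0.0876 with an estimated correlation). Ctsb, a lysosomal protease, differed by 0.95 ± 0.10 (edgeR adjusted p = 7.15e-07). The macrophage score was 1.88 log2 units higher in the same libraries (exact p = 0.00216, the smallest possible).

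Cholesterol synthesis enzymes were lower in 14 of 20 cases with 6 not passing, and 15 were lower when adjusted over the list alone (median -0.32, camera adjusted p = 9.53e-05, adjusted p = 0.612 with an estimated correlation). Hmgcs1 differed by -0.67 ± 0.11 and Msmo1, a methylsterol oxidase, by -0.65 ± 0.13 (edgeR adjusted p = 1.09e-04 and 5.85e-04). Without hIAPP 5 and hIAPP 6, 8 enzymes were lower and 1 higher (median -0.26). Among sterol uptake and SREBP control genes 4 were higher and 1 lower, as when adjusted over the list alone (camera adjusted p = 0.413). Scap, which escorts the SREBP transcription factors, differed by 0.35 ± 0.07 (edgeR adjusted p = 5.51e-04). Among efflux, esterification and oxysterol genes 6 were higher and 2 lower, and 6 and 3 when adjusted over the list alone (camera adjusted p = 0.231). Apoe was higher by 1.74 ± 0.09 (edgeR adjusted p = 3.04e-11) and Abcg1, a sterol exporter, by 0.46 ± 0.07 (edgeR adjusted p = 1.76e-05).

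Beta cell identity genes were higher in hIAPP than in rIAPP in 16 of 21 cases, with 5 not passing and 17 higher when adjusted over the list alone (median 0.74, camera adjusted p = 1.05e-08, adjusted p = 0.273 with an estimated correlation). Glp1r, the GLP-1 receptor, differed by 1.67 ± 0.16 and Nkx6-1, a beta cell transcription factor, by 0.73 ± 0.09 (edgeR adjusted p = 1.68e-07 and 2.29e-06). The potassium channel genes Kcnj12 and Kcng3 differed by 3.73 ± 0.19 and 3.86 ± 0.31 (edgeR adjusted p = 1.56e-11 and 1.01e-08), with hIAPP means of 8.59 and 7.40 CPM near the WT means of 11.3 and 8.60. Endothelial markers were lower in 12 of 12 cases, as when adjusted over the list alone (camera adjusted p = 1.05e-08, adjusted p = 0.0876 with an estimated correlation). Tek, an angiopoietin receptor, differed by -0.70 ± 0.08 (edgeR adjusted p = 1.05e-06). Of 10 ductal markers 4 were lower and 6 not passing, 4 also when adjusted over the list alone (camera adjusted p = 0.00213, adjusted p = 0.108 with an estimated correlation). Tspan8, a tetraspanin, differed by -1.87 ± 0.10 (edgeR adjusted p = 3.03e-11). Of 43 cytosolic ribosomal proteins 19 were lower and 24 not passing, with 24 lower when adjusted over the list alone (camera adjusted p = 3.66e-06, adjusted p = 0.633 with an estimated correlation). Rpl4 differed by -0.29 ± 0.07 (edgeR adjusted p = 0.00283). Of 15 heat shock genes 2 were higher and 13 not passing, with 1 when adjusted over the list alone (camera adjusted p = 0.0257, adjusted p = 0.673 with an estimated correlation). Integrated stress response genes had 4 higher and 1 lower, and 2 and 1 when adjusted over the list alone (camera adjusted p = 0.121). Over all genes 5586 passed, 2730 higher and 2856 lower in hIAPP, of which 615 and 665 differed at least 2-fold, and 9 of the 32 lists were called. The acinar scores of hIAPP and rIAPP differed by -0.45 (exact p = 0.370).

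The comparison of rIAPP with WT asked what a transgene for the rodent peptide changed. The islets held less RNA of beta cell identity genes and more RNA of stress response genes, a rise that shrank with the acinar score as a covariate, and of acinar, mesenchymal and endothelial markers. Mafa averaged 49.7 ± 10.7 CPM in rIAPP and 305 ± 50.9 in WT (SD, n = 6), a log2 fold change of -2.62 ± 0.19 (edgeR adjusted p = 2.79e-09), and Glp1r fell by 1.99 ± 0.17 on the log2 scale (edgeR adjusted p = 1.71e-08). Aass, an enzyme of lysine breakdown, averaged 70.8 ± 15.1 CPM in rIAPP and 2.46 ± 0.493 in WT (log2 4.85 ± 0.18, edgeR adjusted p = 2.40e-13). For each of these 3 genes all rIAPP libraries lay on the same side of all WT libraries.

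Of 21 beta cell identity genes, 20 fell, none rose and 1 did not pass, with 20 lower when adjusted over the list alone (median -1.07, camera adjusted p = 2.90e-16, adjusted p = 0.312 with an estimated correlation). Abcc8 fell by 1.34 ± 0.09 and Nkx6-1 by 0.97 ± 0.09 on the log2 scale (edgeR adjusted p = 5.41e-10 and 5.49e-08). Kcnj12, an inward rectifier potassium channel, fell by 4.13 ± 0.19 and the urea transporter gene Slc14a2 by 4.40 ± 0.46 (edgeR adjusted p = 3.87e-12 and 3.18e-07). Among the genes with the largest rise, Opcml, a neural adhesion molecule, rose by 4.37 ± 0.20, and C1ql3, a secreted synaptic protein, by 6.08 ± 0.38 from 0.0880 CPM in WT (edgeR adjusted p = 2.21e-12 and 3.44e-10). Iapp differed by 0.19 ± 0.11 (95% interval -0.04 to 0.43, edgeR adjusted p = 0.234). The labels do not say which rodent's sequence the transgene carries, so this value does not check the genotype either. Integrated stress response genes rose in 21 of 24 cases with 3 not passing, and 22 were higher when adjusted over the list alone (median 0.57, camera adjusted p = 3.12e-09, adjusted p = 0.429 with an estimated correlation). Acinar scores were also higher in rIAPP, by 2.11 (exact p = 0.00216), and with that score as a covariate 5 stress response genes passed (median 0.25). Sesn2, a stress-induced regulator of nutrient signalling, rose by 0.87 ± 0.10 (edgeR adjusted p = 1.62e-06), and Nupr1, a stress-induced nuclear protein, by 2.57 ± 0.34 (edgeR adjusted p = 8.69e-06). Among p53 targets 6 of 14 rose and 8 did not pass, 6 also when adjusted over the list alone (camera adjusted p = 0.0335, adjusted p = 0.503 with an estimated correlation).

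Acinar markers rose in 23 of 23 cases, as when adjusted over the list alone (median 2.27, camera adjusted p = 6.56e-11, adjusted p = 0.503 with an estimated correlation). The lipase gene Cel rose by 2.25 ± 0.41 (edgeR adjusted p = 2.98e-04). Endothelial markers rose in 12 of 12 cases, as when adjusted over the list alone (median 0.33, camera adjusted p = 9.02e-06, adjusted p = 0.429 with an estimated correlation). Pecam1, a junction protein of endothelium, rose by 0.48 ± 0.07 (edgeR adjusted p = 3.95e-05). Stellate and mesenchymal markers rose in 9 of 12 cases with 3 not passing, 9 also when adjusted over the list alone (camera adjusted p = 2.87e-05, adjusted p = 0.503 with an estimated correlation). Dcn, a matrix proteoglycan, rose by 1.17 ± 0.15 (edgeR adjusted p = 5.36e-06). Macrophage markers fell in 7 of 13 cases and 1 rose, with 5 not passing and the same counts when adjusted over the list alone (camera adjusted p = 0.0335, adjusted p = 0.689 with an estimated correlation). C1qa fell by 1.01 ± 0.10 on the log2 scale, and Mrc1, the mannose receptor of tissue macrophages, rose by 0.81 ± 0.14 (edgeR adjusted p = 1.77e-07 and 1.25e-04). Cytosolic ribosomal proteins rose in 21 of 43 cases with 22 not passing, 23 when adjusted over the list alone (camera adjusted p = 6.97e-07, adjusted p = 0.503 with an estimated correlation). Rpl10a rose by 0.36 ± 0.06 (edgeR adjusted p = 9.47e-05).

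Cholesterol synthesis enzymes had 3 of 20 lower, none higher and 17 not passing, and none passed when adjusted over the list alone (median -0.11, camera adjusted p = 0.151, and 0.0313 without rIAPP 4). Among them were Mvk and Lss, with log2 fold changes of -0.32 ± 0.11 and -0.23 ± 0.08 (edgeR adjusted p = 0.0376 and 0.0403). Sterol uptake and SREBP control genes had 4 higher and 7 lower, as when adjusted over the list alone (camera adjusted p = 0.258). Srebf1, a transcription factor of lipid synthesis, had a log2 fold change of -0.55 ± 0.10 (edgeR adjusted p = 3.29e-04). Efflux, esterification and oxysterol genes had 3 higher and 3 lower, and 4 and 4 when adjusted over the list alone (camera adjusted p = 0.591), and their median (-0.01) and mean (0.21) differed in sign. Among them were the exporter Abcg1 at -0.43 ± 0.07 and the oxysterol hydroxylase Cyp7b1 at 0.84 ± 0.10 (edgeR adjusted p = 4.00e-05 and 3.36e-06). Over all genes 5417 passed, 2860 higher and 2557 lower, of which 825 and 508 changed at least 2-fold, and 8 of the 32 lists were called, none with an estimated correlation. With the acinar score as a covariate 2226 genes passed, 15 of them beta cell identity genes that were lower (median -0.91).

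Among the genes that changed in hIAPP against both other genotypes, the 10 with the smallest p included Sema5a, Snhg18 and several genes that macrophages express. Of these 10 only Lyz2 is on the macrophage list, and the whole set was not tested for a theme. Snhg18, a long noncoding RNA gene, averaged 94.2 ± 10.3 CPM in hIAPP, 6.45 ± 0.339 in WT and 10.7 ± 0.923 in rIAPP (SD, n = 6), with log2 fold changes of 3.87 ± 0.08 and 3.14 ± 0.08 (edgeR adjusted p = 4.27e-18 and 6.31e-17). Trem2, a lipid-sensing receptor of macrophages, rose by 2.69 ± 0.19 against WT and by 3.50 ± 0.20 against rIAPP (edgeR adjusted p = 1.49e-08 and 9.24e-11), and Mpeg1, a pore-forming protein of macrophages, by 2.20 ± 0.17 and 2.53 ± 0.17 (edgeR adjusted p = 4.15e-08 and 7.99e-10). Lyz2, Apoe, Pla2g7, Gpr34, Cd84 and Trf complete the 10 genes with the smallest p, and for each of the 10 all 6 hIAPP libraries lay above all other libraries. Snhg18 and Sema5a lie side by side on chromosome 15 of GRCm38 (32240568 to 32244662 and 32244813 to 32696341), with 150 bases between them. Of 22 tested genes within 2 Mb around them, 5 changed in the same direction against both genotypes, all lower, and 1 more changed in opposite directions. The 5 were Cmbl (-1.41 against WT), Sdc2 (-0.29), Cpq (-0.79), Tspyl5 (-0.62) and Mtdh (-0.19), which were singled out after their values were seen.

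**Figure D3:**
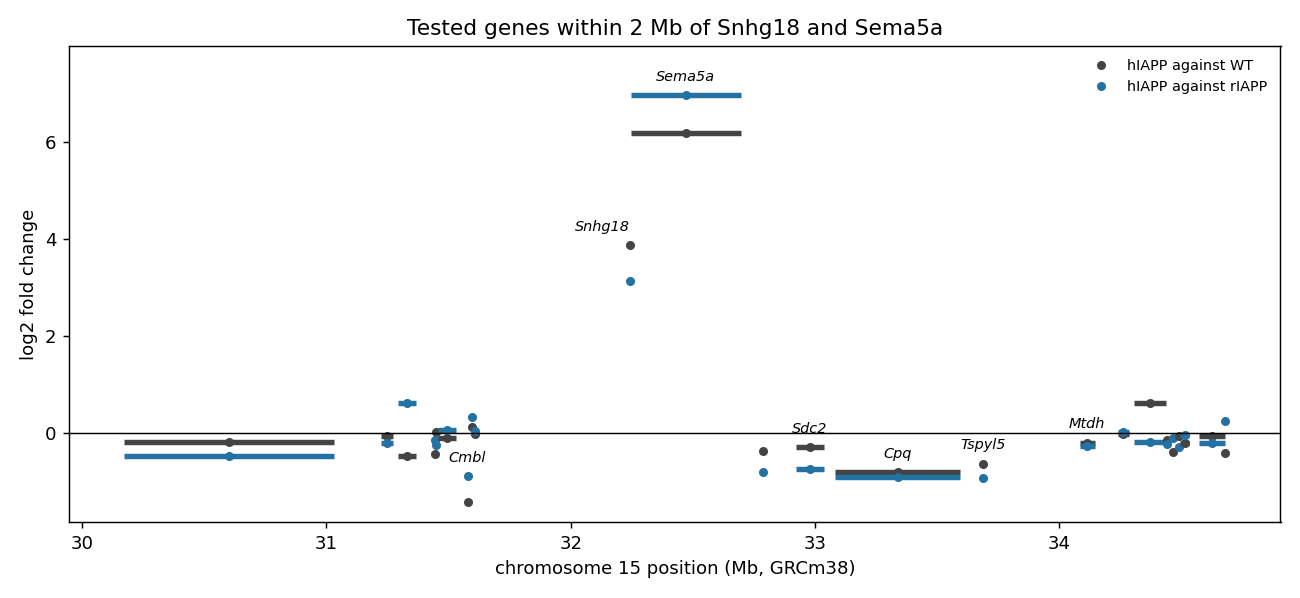
Log2 fold change in hIAPP against WT (grey) and against rIAPP (blue) for tested genes around Sema5a and Snhg18, by position on chromosome 15 in Mb, with bars for the extent of each gene. Sema5a and Snhg18 lie above all their neighbours, and the 5 neighbours that changed in the same direction against both genotypes are lower.

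In all, 1291 genes changed the same way against both, 711 higher and 580 lower, and 313 changed in opposite directions. Independence gave 227 and 215, and 10 simulations of unchanged groups that share the hIAPP libraries gave 0 and 0 by edgeR. The simulations held no changed genes and drew each gene on its own, so a count near 0 was fixed in advance. Sharing libraries raises the correlation of fold changes (0.358 observed, 0.510 with no change), so the covariances were compared, at 0.101 observed and 0.0420 simulated. With the hIAPP libraries split 3 and 3 so that none was shared, the median over 20 splits was 391.5 higher (at least 345) and 180 lower (at least 151). Each comparison then held only 3 hIAPP libraries, and independence was not computed for these lists. The split counts are therefore not comparable with 227 and 215. Given the acinar covariate, 438 genes passed, and without hIAPP 5 and hIAPP 6 770 passed.

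The overlap of the hIAPP and rIAPP changes against WT asked which genes moved with either transgene. Nupr1, Slc7a11, a cystine transporter, and other stress response genes rose in both, as did Aldh1a3 (36.1 ± 10.9 CPM in hIAPP, 31.5 ± 11.6 in rIAPP and 3.27 ± 1.16 in WT, SD, n = 6). Mafa, Npy and Nnat had lower means in both than in WT. Nnat averaged 203 ± 78.1 CPM in WT, 66.5 ± 24.0 in hIAPP and 27.8 ± 6.61 in rIAPP. Both comparisons called 1347 genes in the same direction, 749 higher and 598 lower, and 197 in opposite directions. Independence gave 238 and 193 and simulated unchanged groups 0 and 0 by edgeR, again a count near 0 that was fixed in advance. The covariance of fold changes was 0.103, against 0.0400 simulated, and the correlation 0.365, against 0.493 simulated. With the WT libraries split 3 and 3, the median over 20 splits was 336 higher (at least 258) and 208 lower (at least 169). Each comparison then held only 3 WT libraries, so these counts are not comparable with 238 and 193. Acinar marker scores were higher in both genotypes, and with that score as a covariate the overlap was 228 genes, and without hIAPP 5 and hIAPP 6 it was 749.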

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

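The acinar covariate was chosen beforehand for counts of genes, whereas its use for counts of list members and the other tests in this part were set out only after the results were seen. The 177 genes checked, which include some that the text does not discuss, and each list score and library measure were searched for a library that stood apart from the other 5 of its genotype, by Dixon's gap ratio at its 95% critical value. This met 35 of 651 checks (29 of 531 for genes, 6 of 96 for lists, 0 of 24 for library measures), and chance gives about 1 in 20. WT 5 stood apart in 9 of them and rIAPP 1 in 5. All values that follow are log2 CPM.

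WT 5 was the lowest WT library for Abcg1 (6.08), Cd22 (-1.11), Ndufv2 (5.21), Psmd1 (6.27) and Rpl14 (8.004). It was also lowest for the list scores of ER translocon genes (6.39), proteasome genes (5.23), alpha cell markers (5.03) and cytosolic ribosomal proteins (6.74). WT 6 was the highest WT library for Egfl7 (5.09), Hs3st5 (1.28) and the beta cell identity score (9.38). Among rIAPP libraries, rIAPP 1 was lowest for Emcn (5.73), Hba-a1 (3.19), Hbb-bs (3.07), Hbb-bt (-1.31) and Rarres1 (1.59), and rIAPP 6 for Bbc3 (1.80), Phlda3 (0.995), Plvap (7.31) and Trf (2.52). The library rIAPP 3 was lowest for Fcer1g (0.53) and highest for Sema5a (3.15), rIAPP 5 was lowest for Derl3 (2.16) and Il7r (-1.63), and rIAPP 4 was highest for Uqcrq (3.92). Among hIAPP libraries, hIAPP 5 was highest for Cd4 (2.24) and Ppp1r1b (0.74) and lowest for Rims2 (6.50). The library hIAPP 6 was highest for Trib3 (4.39) and lowest for the proteasome score (5.30). The library hIAPP 3 was highest for Lpcat3 (5.64) and Rprml (-0.49), and hIAPP 4 was lowest for Pramel34 (-0.44) and Vstm2a (-1.25).

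Cholesterol synthesis enzymes were lower in hIAPP, and acinar RNA is unlikely to be the whole cause, since the score was lower in hIAPP than in rIAPP (-0.33, exact p = 0.00649) while the acinar scores of these genotypes differed by -0.45 (exact p = 0.370), although as a median over the list the first difference was -0.09 (exact p = 0.184). A lower share of beta cells alone would raise the markers of every other cell type. Endothelial markers were lower in hIAPP than in WT both as a mean (-0.16, exact p = 0.0152) and as a median over the list (-0.25, exact p = 0.00216). Delta and PP markers (-0.22, exact p = 0.00866) and ductal markers (-0.44, exact p = 0.00216) were clearly lower only as means (medians -0.17, exact p = 0.0584, and -0.03, exact p = 0.773). Erythroid (-0.837), alpha (-0.101) and adipocyte (-0.0404) mean scores were also lower. Acinar (1.66), macrophage (1.55), lymphocyte (0.909), stellate (0.577) and Schwann (0.431) mean scores were higher. Each cell type can move on its own, so a lower share of beta cells was not excluded. With all libraries thinned to the smallest total, 16 enzymes were still lower (median -0.49). In that run 3189 genes passed in all, 3054 of them among the 3208. Thinning keeps each gene's share of its library on average, so this result was all but fixed in advance. A bias tied to depth was therefore not excluded. Chance was not firmly excluded for the list against WT, as 3 of 100 splits of these libraries and 4 of 100 regroupings of all 18 (all 4 in the first 60 drawn), the real grouping included in each count, had a camera adjusted p as small as the real 2.47e-11, the smallest others being 2.15e-15 and 2.48e-19, nor was it against rIAPP (20 of 100 splits, real 9.53e-05, smallest other 4.87e-15) or for rIAPP against WT (48 of 100, real 0.151, smallest other 6.97e-15). Many of the other regroupings of all 18 libraries gave this list a camera adjusted p under 0.05 for hIAPP against WT. A call at the preset correlation is therefore weak evidence by itself. Chance, acinar RNA in part and a lower share of beta cells remain open. The same holds for a bias tied to depth and for a difference in preparation between the groups. That the human transgene may lower these enzymes in beta cells is a further hypothesis, not tested.

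Sema5a and Snhg18 were far higher in hIAPP than in either genotype. RNA of macrophages is an unlikely source, since over the 6 hIAPP libraries the slope of log2 Sema5a on log2 Lyz2 was 0.211 (95% interval -0.05 to 0.473) where a shared source needs about 1, and the Snhg18 slope was -0.32 (-0.54 to -0.09). A change of the wider chromosome region cannot be told apart from one confined to the pair, because 22.7% of the neighbours changed in the same direction against both genotypes, against 6.38% of all genes, at percentile 98.8 of 17246 windows, these 5 all downwards. The median change of the neighbours lay at percentile 81.3, and the share was made the deciding value after that median had been seen. A candidate explanation that stays untested is that the human transgene or DNA carried with it lies in this region, since the labels give no insertion site.

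Beta cell identity genes were lower in rIAPP than in WT. With the acinar score as a covariate 15 of the genes were still lower, with a median of -0.91. All rIAPP acinar scores (6.50 to 8.46) lay above all WT scores (4.49 to 6.37), so this fit extrapolates and cannot decide how much acinar RNA contributes. Acinar RNA is still unlikely to be the whole cause. The beta cell identity score was 0.717 higher in hIAPP than in rIAPP (exact p = 0.00433), while their acinar scores differed by -0.45 (exact p = 0.370). That p does not show equal acinar RNA, and the difference lies in the direction that acinar RNA would give. However, rIAPP 3 and rIAPP 5 had lower acinar scores (6.68 and 6.50) than hIAPP 5 and hIAPP 6 (7.58 and 8.31). Their beta cell identity scores were lower too (8.05 and 8.09, against 8.52 and 8.62). A lower share of beta cells alone would raise the other cell types alike. Endothelial and macrophage markers instead moved apart by 0.661 log2 units (exact p = 0.00216, the smallest possible). Macrophages can change in number on their own, so this gap does not exclude a lower share. Acinar (2.11), stellate (0.893), adipocyte (0.843), alpha (0.523), endothelial (0.333), Schwann (0.308) and ductal (0.108) scores were higher than in WT. Erythroid (-0.707), lymphocyte (-0.515), macrophage (-0.328) and delta and PP (-0.131) scores were lower. An effect of the rodent transgene on beta cells may remain as a hypothesis, and a difference in breeding or isolation between the lines was not tested, since the labels give no batch.

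For each comparison 1 of 100 splits, the real one, gave as many genes by edgeR. Chance is therefore an unlikely source of these counts. Splits of libraries cannot tell genotype from a difference in preparation between the groups. The real counts and the highest of the other splits were 3208 and 2533 for hIAPP against WT, 5586 and 1519 for hIAPP against rIAPP, and 5417 and 2564 for rIAPP against WT. In the first 60 splits drawn, the highest other count for hIAPP against rIAPP was 233. Regroupings of the 18 libraries gave at most 0 genes changed in hIAPP against both (real 1291) and at most 0 in the overlap (real 1347). Most of these regroupings called no gene in any comparison, so a joint count of 0 was all but fixed in advance. They do not settle chance for the joint counts. Splits of 1 pair of genotypes, which leave the other genotype in place, gave up to 1159 genes against both and up to 1311 in the overlap.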

How the results depend on the processing

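The runs without hIAPP 5 and hIAPP 6, with thinned counts, and with medians for scores other than cell type, cholesterol synthesis and beta cell identity were chosen only after the data were seen. Counts are given in the order hIAPP against WT, hIAPP against rIAPP, rIAPP against WT, changed in hIAPP against both, and overlap of the changes against WT. At an adjusted p under 0.01 they were 1490, 3617, 3598, 590 and 584, and against a fold change of 1.2 they were 835, 2379, 2430, 375 and 320, as stricter thresholds must give fewer. With the acinar score as a covariate they were 792, 5516, 2226, 438 and 228, and 712 of the 792 were among the 3208. All rIAPP acinar scores lay above all WT scores, so calls lost with this covariate cannot be ascribed to acinar RNA alone. Without hIAPP 5 and hIAPP 6, with fewer libraries, 1675 passed against WT (1538 of them among the 3208), 770 against both and 749 in the overlap. DESeq2 called 3831, 6123 and 5920 genes and limma-voom 3940, 6762 and 6838 in the first 3 comparisons. With library totals alone 86.7% of genes called for hIAPP against WT were higher (52.5% with TMM) and 76.4% for rIAPP against WT (52.8% with TMM), and the median of all genes shifted to 0.11 and 0.10. For the cholesterol synthesis list, the call was lost with an estimated correlation against WT (0.156) and against rIAPP (0.612), and the cause was not tested beyond that correlation.

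Leaving out each library in turn gave 2377 to 3919, 4865 to 5876, 4711 to 5612, 966 to 1662 and 1004 to 1500 genes. The cholesterol list kept its side of the threshold for hIAPP against WT (9.83e-13 to 3.61e-09) and against rIAPP (6.39e-06 to 6.78e-04), but for rIAPP against WT it ran from 0.0313 without rIAPP 4, where it was called, to 0.349, and the cause was not tested. As a median in place of the mean over the list, 13 of 96 score differences changed sign, and the cause was not tested. For hIAPP against WT these were sterol uptake (-0.12 to 0.12) and exocytosis (-0.10, exact p = 0.0130, to 0.0341, exact p = 0.409). For hIAPP against rIAPP they were fatty acid genes (to 0.15), ER chaperones (to -0.0896), disallowed genes (to 0.21), immediate early genes (to 0.0135), Schwann markers (to -0.20) and histones (to 0.14). For rIAPP against WT they were cholesterol efflux (0.22, exact p = 0.00216, to -0.19, exact p = 0.0584), glycolysis (0.10 to -0.20, exact p = 0.00216), interferon (to 0.0750), lymphocyte markers (to 0.14) and histones (to -0.13). Among 250 named gene results none reversed under any setting run. Calls were lost for 61 with the acinar covariate, 61 against a fold change of 1.2, 25 at an adjusted p under 0.01, 24 without hIAPP 5 and hIAPP 6, 19 with library totals alone, and 0 with thinned counts or DESeq2. Over all runs that left out 1 library, 86 of 4500 were lost, and Lss and Mvk in rIAPP against WT were among those lost most often. The covariate for sex was not run. At this depth the simulated data showed that few changes of 1.2-fold were found.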

Other observations

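The genes named here were chosen only after their values were seen. Alpha cell markers split in rIAPP islets. Gc, the vitamin D binding protein, rose from 65.6 CPM in WT to 411 in rIAPP (log2 2.65 ± 0.08, edgeR adjusted p = 2.59e-15), and Slc38a5, an amino acid transporter of proliferating alpha cells, from 5.71 to 34.2 (2.58 ± 0.13, edgeR adjusted p = 9.82e-12). Over the 8 alpha cell markers 2 were higher and 1 lower for rIAPP against WT (camera adjusted p = 0.258), with a median of -0.05 and a mean of 0.53. Neurog3, the transcription factor of endocrine progenitors, averaged 8.95 CPM in rIAPP, 1.76 in hIAPP and 2.25 in WT (rIAPP against WT 1.99 ± 0.18, edgeR adjusted p = 6.46e-08). Sytl4, a docking protein of insulin granules, and Usp18, which removes ISG15, were lower in rIAPP than in WT, by log2 fold changes of -1.65 and -1.42.

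Several gene groups did not pass the camera test, and their members higher and lower are given as called over all genes. Adjusted over the list alone, each of these counts differed by at most 2. In hIAPP against WT, ER translocon and N-glycosylation genes had 2 higher and 0 lower (camera adjusted p = 0.566), beta cell disallowed and immature genes 3 and 3 (0.456), glycolysis and HIF targets 0 and 2 (0.214), cell cycle genes 1 and 0 (0.249) and immediate early genes 3 and 0 (0.197). Alpha cell markers had 1 and 1 (camera adjusted p = 0.581), delta and PP cell markers 0 and 1 (0.0628), and the 2 adipocyte markers (0.828), 43 ribosomal proteins (0.711) and 13 histones (0.786) had none that passed.

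In hIAPP against rIAPP, fatty acid genes had 6 higher and 5 lower (camera adjusted p = 0.879), ER chaperones 6 and 4 (0.984), ER translocon genes 0 and 3 (0.136), proteasome genes 1 and 0 (0.385) and exocytosis genes 6 and 4 (0.503). Disallowed genes had 2 and 4 (camera adjusted p = 0.483), glycolysis genes 1 and 4 (0.0837), respiratory chain genes 0 and 2 (0.503), cell cycle genes 3 and 2 (0.110), p53 targets 2 and 1 (0.712), interferon genes 2 and 7 (0.174) and immediate early genes 1 and 2 (0.483). Alpha cell markers had 0 and 2 (camera adjusted p = 0.0648), delta and PP markers 0 and 0 (0.527), acinar markers 0 and 0 (0.153), stellate markers 2 and 2 (0.413), Schwann markers 1 and 1 (0.504), adipocyte markers 0 and 2 (0.148), erythroid markers 0 and 0 (0.801) and histones 1 and 2 (0.801). Median and mean differed in sign for fatty acid genes (0.02 and -0.0015), ER chaperones (-0.05 and 0.05) and histones (-0.01 and 0.0059).

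In rIAPP against WT, fatty acid genes had 3 higher and 10 lower (camera adjusted p = 0.0503), ER chaperones 9 and 4 (0.0513), ER translocon genes 5 and 0 (0.0503), exocytosis genes 2 and 8 (0.0503) and Schwann markers 2 and 0 (0.0523). Heat shock genes had 2 and 1 (camera adjusted p = 0.895), proteasome genes 0 and 2 (0.258), autophagy and lysosome genes 3 and 7 (0.258), disallowed genes 6 and 4 (0.165), glycolysis genes 6 and 3 (0.388), respiratory chain genes 0 and 2 (0.441) and cell cycle genes 2 and 1 (0.388). Interferon genes had 3 and 5 (camera adjusted p = 0.708), with a median of 0.03 and a mean of -0.08, and immediate early genes 2 and 0 (0.102). Delta and PP markers had 0 and 0 (camera adjusted p = 0.441), ductal markers 3 and 2 (0.441), lymphocyte markers 0 and 2 (0.165), adipocyte markers 1 and 0 (0.165), erythroid markers 0 and 3 (0.0577) and histones 1 and 0 (0.596).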
